A study of Rattus norvegicus with 12 samples.

How the data were processed

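RNA was measured in whole urinary bladder of female Wistar rats, a common outbred laboratory strain, from 3 uninjured controls and from 3 rats each at 7, 14 and 28 days after the spinal cord had been cut through at thoracic segment 10. Per the labels, total RNA was depleted of ribosomal RNA with a RiboMinus kit, made into libraries by the Illumina TruSeq protocol and sequenced as single reads of 50 bases on an Illumina HiSeq. The submitters' processing notes name bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.2 and the rat build rn6 without saying what each did. Whether counting used the strand is not given in the sources used here, and another gene overlaps 13 of the 58 named genes examined, 5 of them on the same strand. These are Tnn, Car14, Slfn4, Ntrk2, Cxcl6, Krt20, Cntnap2, Duox2, Gkn3, Fosb, Timp1, Myh11 and Il6. Only over Il6 does the other gene hold more counts, and Il6 is treated as uncertain. Reads this short cannot be placed between near-identical copies, which makes the haemoglobin, mast cell protease, gastrokine and rat MHC (RT1) families uncertain as well.

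The authors deposited read counts per gene and read counts per non-coding transcript, whole numbers with no normalization, per the file headers and the values. In the transcript table the isoforms of a gene can hold the same reads, so those transcripts are not independent of one another. The authors also deposited tables of their own comparisons of non-coding RNA with control, which hold a log2 fold change, a p-value and a q-value per transcript, per the file headers. Per the values in those deposited tables, the authors' signal columns equal the raw count divided by 1 size factor per library in each comparison, and the transcripts marked as different have an absolute log2 fold change of at least 1 and a q-value under 0.05. Deposited gene lengths in bases, per the file headers, were not used. The gene table lists 40154 genes and the transcript table holds 15516 transcripts of 11104 genes. A deposited transcript table of mRNAs was not used, since a read is counted there for every isoform. Gene names are those of the authors' tables. A RefSeq gene table of the rat assembly GRCr8 gave a current symbol to 3017 transcripts, 746 of them tested, and was used for names only, so that Meg3 and Xist below are listed in the authors' table as RGD1566401 and LOC100911498. All coordinates are those of the authors' tables, on rn6 per the submitters' processing notes.

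Groups came from the sample titles. Genes were tested with edgeR 4.0.16 in R 4.3.3: genes passing filterByExpr (minimum count 10, minimum total 15) were kept, libraries were scaled by TMM, and 1 quasi-likelihood model over all 12 libraries gave each comparison. The 3 days were each compared with control, and the days with one another. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. Unless another tool is named, an adjusted p for a gene or transcript is from that test. Non-coding transcripts were tested in the same way with the library sizes and TMM factors of the gene table. CPM are read counts scaled to library size after TMM. A log2 fold change from edgeR is given with an approximate standard error (SE). This SE is the absolute log2 fold change divided by the square root of the F statistic of its test. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over all 102 list tests (34 lists at 3 days). Each list was tested again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance one way. The count of members adjusted over the list alone is given beside the count over all genes tested. Where a group held 1 to 9 counts of a named and called gene or transcript in total, the ratio of summed counts is given with an exact 95% interval that covers counting error only. Tables were handled with the data.table package (version 1.17.8), and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

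The groups, tests, gene lists, named genes and main alternatives were fixed before the data were examined. For each day against control the text names the 6 largest rises and 6 largest falls among genes with a symbol, an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 5 CPM over all libraries and all 3 injured libraries outside the range of the controls. Between successive days it names 5 in each direction by the same rule, and of the non-coding transcripts 4 in each direction at a mean of at least 1 CPM. From each list described it names up to 4 members with the smallest p, and 17 genes and a list of long non-coding RNAs were fixed by name. Some genes that these rules select are not reported here. The alternatives were DESeq2 1.42.0, the RLE size factors of edgeR, no expression filter, a mean of at least 5 CPM, an absolute log2 fold change of at least 1, a model of only the 2 groups compared, a block for the replicate number, and leaving out each library in turn. For transcripts, own library totals, 1 transcript per gene and long non-coding types alone were added after the data had been seen.

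The libraries held 26.3 to 30.7 M counts. Tested on simulated counts with the means, spread and library sizes of the real ones and 200 changed genes, edgeR recovered 13.4%, 47.8% and 77.3% of genes changed by 1.5, 2 and 4 times at day 7, with 7 false calls among 99. At day 14 the shares were 11.9%, 50.8% and 65.2% with 6 false calls among 91, and at day 28 16.4%, 37.3% and 77.3% with 5 among 92, over 16982 genes each. DESeq2 gave 25, 23 and 35 false calls among 145, 126 and 138 on such data, and recovered 71.6%, 55.2% and 44.8% of genes changed by 2 times. For non-coding transcripts edgeR recovered 28.4%, 22.4% and 43.3% of those changed by 2 times at days 7, 14 and 28. In simulated lists the 1 changed list was called and 0 of 98 other tests were, by camera at either correlation and by fry. Correlation between genes was not simulated, so false list calls it causes could not show. The labels call the samples of a group separate, and the p-values measure the spread between them, part of which may be technical.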

Results

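The series holds the bladder transcriptome of female rats at 3 times after a complete cord transection, an injury that leaves a neurogenic bladder, with uninjured rats as controls. Each of the 4 groups had 3 libraries (n = 3 throughout). Control libraries held 28.4, 27.0 and 27.4 M counts and day-7 libraries 28.8, 30.6 and 30.7 M. Day-14 libraries held 26.3, 28.7 and 28.3 M and day-28 libraries 29.5, 28.8 and 29.5 M. Of the genes listed, 17687 passed the filter. Group levels below are mean CPM ± SD, and changes are log2 fold changes ± SE against control unless another group is named. Gene coordinates are on rn6 per the submitters' notes.

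The first principal component of log2 CPM held 35.2% of the variance and the second 22.6%. On the first, controls lay at −67.8 to −65.4, day 14 at −36.8 to −0.491, day 28 at 9.87 to 39.3 and day 7 at 37.1 to 68.4. Mitochondrially encoded transcripts made up 6.61% ± 0.455 of counts in controls, 4.59% ± 0.284 at day 7, 5.91% ± 0.529 at day 14 and 6.43% ± 0.494 at day 28. Haemoglobin transcripts were 0.160% ± 0.114 in controls, 0.0569% ± 0.0216 at day 14 and 0.0813% ± 0.0136 at day 28. At day 7 they were 1.14% ± 1.52, with 0.156%, 0.370% and 2.89% in replicates 1, 2 and 3. Pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 16.1 to 125), so each library counted as 1 sample. The median SD of log2 CPM between replicates was 0.163 in controls, 0.222 at day 7, 0.231 at day 14 and 0.223 at day 28.

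The comparison at day 7 asked which transcripts differed in the first week after injury. Tnn (chromosome 13, 77829384 to 77896831), which encodes the matrix glycoprotein tenascin-N, rose from 0.143 ± 0.0621 to 142 ± 115 CPM (9.92 ± 1.00, adjusted p = 0.000128). Grem1 (chromosome 3, 105203309 to 105214989), a secreted antagonist of bone morphogenetic proteins, rose from 1.54 ± 0.338 to 268 ± 91.7 CPM (7.44 ± 0.66). Cilp (chromosome 8, 70760922 to 70775891), a matrix protein first known from cartilage, rose from 6.37 ± 1.15 to 850.2 ± 468 CPM (7.06 ± 1.00). Osteopontin (Spp1, chromosome 14, 6673686 to 6679965) rose by 7.55 ± 0.88. The largest named fall was that of Cyp1a1 (chromosome 8, 62472087 to 62478122), a target of the aryl hydrocarbon receptor, from 64.8 ± 39.6 to 0.386 ± 0.300 CPM (−7.38 ± 1.16). The aldehyde dehydrogenase Aldh3a1 (chromosome 10, 47490168 to 47499855) stood at −4.55 ± 0.42 and Mamdc2 (chromosome 1, 241071110 to 241223798) at −4.44 ± 0.62. Myocilin (Myoc, chromosome 13, 80517531 to 80527928) stood at −3.90 ± 0.57, the secreted phospholipase Pla2g2a (chromosome 5, 157282650 to 157285295) at −3.75 ± 0.52 and the carbonic anhydrase Car14 (chromosome 2, 198010142 to 198017635) at −3.74 ± 0.45. All of these calls held when any 1 library was left out.

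Most tested cell cycle and matrix genes were called higher at day 7. Of the cell cycle genes, 29 of 30 rose (median 3.42, camera adjusted p = 6.65e-20, adjusted p = 0.453 with an estimated correlation, 29 up and 0 down adjusted over the list alone). Among them were the spindle factor Tpx2 (3.71 ± 0.33), the checkpoint kinase Bub1 (2.74 ± 0.27) and cyclin A (Ccna2, 4.48 ± 0.45). The proliferation marker Mki67 (chromosome 1, 207993895 to 208020454) rose by 4.17 ± 0.48. Of the extracellular matrix and fibrosis genes, 25 of 29 rose and 0 fell (median 2.22, camera adjusted p = 8.04e-15, adjusted p = 0.471 with an estimated correlation, 27 up and 1 down adjusted over the list alone). These were led by Tgfb1 (1.67 ± 0.13), fibronectin (Fn1, 3.23 ± 0.31) and Cthrc1 (4.71 ± 0.49). The matrix glycoprotein Tnc (chromosome 5, 79789686 to 79874555) rose by 3.06 ± 0.42 and the metalloproteinase inhibitor Timp1 (chromosome X, 1364771 to 1369451), which overlaps Syn1, by 3.83 ± 0.58. Col1a1 (chromosome 10, 82745801 to 82762790) stood at 19222 ± 3268 against 10273 ± 2049 CPM and missed the threshold (0.90 ± 0.31, adjusted p = 0.0509). Elastic fibre genes rose in 7 of 11 cases (median 1.26, camera adjusted p = 0.000994, adjusted p = 0.615 with an estimated correlation, 7 up and 0 down adjusted over the list alone). Emilin1 (1.61 ± 0.13) and Ltbp1 (1.54 ± 0.15), both of the microfibril network, had the smallest p. Endothelial markers rose in 13 of 14 cases (median 1.31, camera adjusted p = 5.15e-09, adjusted p = 0.453 with an estimated correlation, 14 up and 0 down adjusted over the list alone). They included the transcription factor Erg (2.05 ± 0.23) and VE-cadherin (Cdh5, 1.93 ± 0.22). Growth factor and remodelling genes went both ways, 7 up and 6 down of 24 (median 0.57, camera adjusted p = 0.488, 9 up and 7 down adjusted over the list alone). Igfbp3 stood at −3.61 ± 0.29 and the activin subunit Inhba at 3.70 ± 0.52.

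Members of several immune cell lists were called higher at day 7. All 18 of 18 macrophage and myeloid markers rose (median 1.73, camera adjusted p = 1.52e-12, adjusted p = 0.453 with an estimated correlation, 18 up and 0 down adjusted over the list alone). They included Laptm5 (1.60 ± 0.12), Tyrobp (2.11 ± 0.24) and the lysosomal marker Cd68 (chromosome 10, 56268726 to 56270605, 2.1 ± 0.27). Neutrophil markers rose in 5 of 11 cases (median 4.30, camera adjusted p = 0.00458, adjusted p = 0.718 with an estimated correlation, 9 up and 0 down adjusted over the list alone). They included the oxidase subunit Ncf1 (2.21 ± 0.27). Genes of MHC class II presentation rose in 6 of 7 cases (median 1.35, camera adjusted p = 0.00122, adjusted p = 0.615 with an estimated correlation, 6 up and 0 down adjusted over the list alone), with Cd74 at 1.52 ± 0.25. Mast cell markers rose in 5 of 10 cases (median 1.43, camera adjusted p = 0.0111, adjusted p = 0.718 with an estimated correlation, 7 up and 0 down adjusted over the list alone). The chymase Cma1 stood at 3.02 ± 0.36 and the tryptase Tpsab1, of a family with near-identical copies, at 4.90 ± 0.59. Cytokine, chemokine and inflammatory enzyme genes rose in 11 of 28 cases (median 2.09, camera adjusted p = 0.0189, adjusted p = 0.822 with an estimated correlation, 14 up and 0 down adjusted over the list alone). The monocyte attractant Ccl2 rose by 3.53 ± 0.81 and the prostaglandin synthase Ptgs2 by 2.28 ± 0.53. Il6 (chromosome 4, 3043231 to 3047807) had 343 counts against 1 in controls, a ratio of 345 with a 95% interval of 61.5 to 13670.0 (7.98 ± 2.27, adjusted p = 0.0237). It is uncertain, because it overlaps Kmt2c on the same strand, with 76788 counts over all libraries against 472 of Il6. Interferon response genes rose in 6 of 20 cases (median 2.02, camera adjusted p = 0.0111, adjusted p = 0.822 with an estimated correlation, 14 up and 0 down adjusted over the list alone). T and NK cell markers were called in 2 of 16 cases (median 1.11, camera adjusted p = 0.172, 2 up and 0 down adjusted over the list alone) and B and plasma cell markers in 3 of 7 (median 1.45, camera adjusted p = 0.288, 4 up and 0 down adjusted over the list alone). Erythroid markers rose in all 10 of 10 cases (median 3.17, camera adjusted p = 0.00842, adjusted p = 0.755 with an estimated correlation, 10 up and 0 down adjusted over the list alone), with haemoglobin Hba-a1 at 3.34 ± 0.83. Without day-7 replicate 3, the library with 2.89% haemoglobin transcripts, 0 of the 10 erythroid genes were called by edgeR. Il6 lost its call without any 1 control library or day-7 replicate 3 (adjusted p 0.0818 to 0.0900, 0.00143 to 0.0900 over all alternatives). Hba-a1 lost significance without control replicate 1 or 2 or day-7 replicate 3 (adjusted p 0.0505 to 0.0583, 0.000843 to 0.0583 over all alternatives). The interferon list was not called without day-7 replicate 1 (adjusted p 0.0583, 0.00117 to 0.0583 over all alternatives). The log2 fold change moved by over 1.5 times for Ptgs2 (1.35 without day-7 replicate 3) and Hba-a1 (1.47 without day-7 replicate 3).

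Urothelial genes were lower at day 7, with 9 of 25 falling and 0 rising (median −0.48, camera adjusted p = 3.58e-05, adjusted p = 0.615 with an estimated correlation, 0 up and 9 down adjusted over the list alone). These included the regulators Pparg (−0.96 ± 0.12) and Tp63 (−1.03 ± 0.14) and the apical plaque protein Upk1b (−0.66 ± 0.13). Upk2 (chromosome 8, 48772906 to 48774898, −0.48 ± 0.18, adjusted p = 0.0734) and the basal keratin Krt5 (chromosome 7, 143320142 to 143324536, 0.03 ± 0.48, adjusted p = 0.975) missed the threshold. Smooth muscle genes were split, 7 up and 6 down of 23 (median −0.06, mean 0.11, tested direction lower, camera adjusted p = 0.825, 8 up and 9 down adjusted over the list alone). The integrin Itga8 stood at 4.56 ± 0.59 and phospholamban (Pln), which restrains the calcium pump, at −1.94 ± 0.34. Desmin (Des, chromosome 9, 82556574 to 82564288) rose by 1.11 ± 0.25 and smooth muscle actin (Acta2, chromosome 1, 252537614 to 252550394) by 0.79 ± 0.22. The smooth muscle myosin heavy chain Myh11 (chromosome 10, 764421 to 859184) was not called (−0.74 ± 0.31, adjusted p = 0.103). Receptors and channels of contraction and sensation were split, 9 up and 6 down of 39 (median −0.05, mean 0.05, tested direction lower, camera adjusted p = 0.982, 9 up and 8 down adjusted over the list alone). The mechanosensitive channel Piezo2 stood at 3.35 ± 0.31, the endothelin receptor Ednra at 2.40 ± 0.24 and the osmotically and mechanically gated channel Trpv4 at −1.39 ± 0.16. The beta-adrenergic receptor of detrusor relaxation, Adrb3 (chromosome 16, 69003541 to 69006632), was lower (−2.30 ± 0.46). The muscarinic receptors Chrm2 (chromosome 4, 64089028 to 64091090, 0.30 ± 0.25) and Chrm3 (chromosome 17, 63990599 to 64463222, −0.57 ± 0.39) were not called (adjusted p = 0.403 and 0.302). Nor was the purinergic receptor P2rx1 (chromosome 10, 59566268 to 59581328, −0.70 ± 0.40, adjusted p = 0.225). Acta2 lost its call without control replicate 1 or 2 or day-7 replicate 1 or 3 (adjusted p 0.0521 to 0.0684, 0.00236 to 0.0684 over all alternatives).

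Neurotrophic genes went both ways at day 7, 4 up and 3 down of 16 (median −0.03, mean 0.42, tested direction lower, camera adjusted p = 0.525, 4 up and 3 down adjusted over the list alone). Bdnf (chromosome 3, 100768637 to 100819216) rose from 0.310 ± 0.0965 to 16.2 ± 9.54 CPM (5.69 ± 0.71). The GDNF family receptor Gfra1 (−1.78 ± 0.17) and the ciliary neurotrophic factor receptor Cntfr (−2.42 ± 0.33) fell. Schwann cell and myelin genes had 3 up and 6 down of 16 (median −0.76, mean 0.13, tested direction lower, camera adjusted p = 0.225, 3 up and 6 down adjusted over the list alone), with the cadherin Cdh19 at −2.25 ± 0.27. Neuron and autonomic nerve genes had 3 up and 4 down of 12 (median 0.35, mean 0.53, tested direction lower, camera adjusted p = 0.895, 4 up and 4 down adjusted over the list alone), with the neuronal tubulin Tubb3 at 4.90 ± 0.66. Genes of mitochondrial respiration fell in 6 of 27 cases (median −0.16, camera adjusted p = 0.0151, adjusted p = 0.755 with an estimated correlation, 0 up and 5 down adjusted over the list alone), with Cox6c at −0.67 ± 0.08. Genes of fatty acid oxidation and lipid metabolism fell in 6 of 21 cases and rose in 1 (median −0.17, camera adjusted p = 0.0252, adjusted p = 0.604 with an estimated correlation, 1 up and 6 down adjusted over the list alone), with the lipase inhibitor Angptl4 at 1.58 ± 0.27. Circadian clock genes fell in 7 of 17 cases and rose in 1 (median −0.46, camera adjusted p = 0.00605, adjusted p = 0.604 with an estimated correlation, 1 up and 8 down adjusted over the list alone). Nr1d1 (−1.79 ± 0.30) and Hlf (−2.13 ± 0.39), both clock-controlled transcription factors, led them. Immediate early genes rose in 5 of 18 cases (median 1.17, camera adjusted p = 0.0116, adjusted p = 0.792 with an estimated correlation, 5 up and 0 down adjusted over the list alone), with the phosphatase Dusp1 at 1.32 ± 0.30. In all, 4622 genes were called at day 7, 2757 higher and 1865 lower, and 2346 of them had an absolute log2 fold change of at least 1. The count was 3078 without control replicate 1, 3081 without control replicate 2 and 3061 without day-7 replicate 2. The mitochondrial list lost its call without day-7 replicate 1 (adjusted p 0.176, 0.00101 to 0.176 over all alternatives). The lipid metabolism list lost significance without control replicate 1 (adjusted p 0.0551, 0.0191 to 0.0551 over all alternatives). The immediate early list was not called without day-7 replicate 3 (adjusted p 0.257, 0.000466 to 0.257 over all alternatives).

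At day 14 the comparison asked what remained in the second week. Grem1 was still raised (86.9 ± 54.5 CPM, 5.82 ± 0.62, adjusted p = 0.00443). Igfbp3 (chromosome 14, 87457647 to 87465374), a binding protein of insulin-like growth factors, was lower (115 ± 47.4 against 728 ± 113 CPM, −2.67 ± 0.27, adjusted p = 0.00407). Ficolin B (Fcnb, chromosome 3, 6617816 to 6626193), a lectin of myeloid cells, rose by 5.54 ± 1.15 and the granulocyte colony-stimulating factor receptor Csf3r (chromosome 5, 144031353 to 144051966) by 5.44 ± 1.13. The diamine oxidase Aoc1 (chromosome 4, 78496043 to 78515582) rose by 4.58 ± 0.82, Spp1 by 4.45 ± 0.87 and Slfn4 (chromosome 10, 70411686 to 70435162) by 4.30 ± 0.70. Myoc (−2.90 ± 0.53), Aldh3a1 (−2.83 ± 0.38) and the BDNF receptor Ntrk2 (chromosome 17, 5934651 to 6245778, −2.60 ± 0.55) were lower. So was the carboxylesterase Ces1f (chromosome 19, 15081117 to 15126629, −2.16 ± 0.40). Of these, only Grem1, Aldh3a1 and Igfbp3 were called with any 1 library left out. Fcnb lost its call without any 1 control library or day-14 replicate 3 (adjusted p 0.0964 to 0.139, 9.31e-06 to 0.139 over all alternatives). Csf3r lost significance without any 1 control library and with only the 2 groups fitted (adjusted p 0.0572 to 0.139, 6.87e-06 to 0.139 over all alternatives). Aoc1 was not called without any 1 control library (adjusted p 0.0752 to 0.104, 3.75e-06 to 0.104 over all alternatives). Spp1 dropped out without any 1 control library or day-14 replicate 3 (adjusted p 0.0671 to 0.125, 2.15e-05 to 0.125 over all alternatives). Slfn4 lost its call without any 1 control library (adjusted p 0.0743 to 0.0861, 2.27e-07 to 0.0861 over all alternatives). Myoc lost its call without any 1 control library or day-14 replicate 2 or 3 (adjusted p 0.0535 to 0.0916, 1.20e-06 to 0.0916 over all alternatives). Ntrk2 lost significance without any 1 control library or day-14 replicate 1 or 3 (adjusted p 0.0695 to 0.133, 2.45e-05 to 0.133 over all alternatives). Ces1f was not called without any 1 control library or day-14 replicate 2 (adjusted p 0.0559 to 0.0913, 6.27e-06 to 0.0913 over all alternatives). The log2 value moved by over 1.5 times for Csf3r (2.95 without day-14 replicate 3).

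Camera called all immune lists at day 14, fry only macrophage and MHC class II. Macrophage and myeloid markers rose in 7 of 18 cases (median 1.18, camera adjusted p = 1.23e-13, adjusted p = 0.453 with an estimated correlation, 15 up and 0 down adjusted over the list alone), with Laptm5 at 1.01 ± 0.12. Cd68 stood at 52.4 ± 21.3 against 20.9 ± 2.91 CPM (1.32 ± 0.27). Neutrophil markers rose in 4 of 11 cases (median 5.01, camera adjusted p = 0.000381, adjusted p = 0.615 with an estimated correlation, 10 up and 0 down adjusted over the list alone), with Ncf1 at 1.62 ± 0.27. MHC class II genes rose in 3 of 7 cases (median 1.19, camera adjusted p = 2.03e-06, adjusted p = 0.471 with an estimated correlation, 6 up and 0 down adjusted over the list alone), with Cd74 at 1.34 ± 0.25. Mast cell markers rose in 4 of 10 cases (median 1.85, camera adjusted p = 0.000275, adjusted p = 0.604 with an estimated correlation, 6 up and 0 down adjusted over the list alone), with Tpsab1 at 3.94 ± 0.58. The interferon response list was higher with 1 of 20 genes called, Oas1a (3.11 ± 0.70) (median 2.70, camera adjusted p = 2.16e-07, adjusted p = 0.615 with an estimated correlation, 15 up and 0 down adjusted over the list alone). The cytokine and inflammatory enzyme list was higher with 1 of 28 called, Cxcl10 (3.57 ± 0.79) (median 2.51, camera adjusted p = 0.000754, adjusted p = 0.736 with an estimated correlation, 12 up and 0 down adjusted over the list alone). T and NK cell markers were higher as a list with 1 of 16 called, Cd8b (2.89 ± 0.60, 47 against 6 counts, ratio 7.77, 95% interval 3.32 to 22.3) (median 1.20, camera adjusted p = 0.00605, adjusted p = 0.736 with an estimated correlation, 6 up and 0 down adjusted over the list alone). B and plasma cell markers were higher as a list with 1 of 7 called, the kinase Blk (2.95 ± 0.62, 65 against 8 counts, ratio 8.06, 95% interval 3.86 to 19.5) (median 1.00, camera adjusted p = 0.0349, adjusted p = 0.615 with an estimated correlation, 3 up and 0 down adjusted over the list alone). Il6 had 47 counts against 1 (ratio 46.6, 95% interval 7.97 to 1881, adjusted p = 0.316). Cd68 lost its call without any 1 control library or day-14 replicate 2 or 3 and with only the 2 groups fitted (adjusted p 0.0533 to 0.132, 9.96e-05 to 0.132 over all alternatives). Ncf1 lost its call without any 1 control library (adjusted p 0.0743 to 0.0861, 1.03e-06 to 0.0861 over all alternatives). Cd74 was not called without any 1 control library or day-14 replicate 3 (adjusted p 0.0542 to 0.0996, 7.38e-06 to 0.0996 over all alternatives). Tpsab1 dropped out without control replicate 1 or 2 (adjusted p 0.0724 to 0.0737, 1.61e-11 to 0.0737 over all alternatives). Oas1a lost its call without any 1 control library or day-14 replicate 2 or 3, among genes of at least 5 CPM and with only the 2 groups fitted (adjusted p 0.0533 to 0.167, 0.00110 to 0.167 over all alternatives). Cxcl10 lost its call without any 1 control library or day-14 replicate 2 or 3 and among genes of at least 5 CPM (adjusted p 0.0504 to 0.157, 0.000476 to 0.157 over all alternatives). Cd8b lost its call without any 1 control library or day-14 replicate 3 (adjusted p 0.0967 to 0.138, 0.00317 to 0.138 over all alternatives). Blk was not called without any 1 control library or day-14 replicate 2 (adjusted p 0.0736 to 0.138, 0.00221 to 0.138 over all alternatives). The cytokine list dropped out without day-14 replicate 3 (adjusted p 0.0844, 1.74e-07 to 0.0844 over all alternatives). The B cell list lost its call without any 1 control library or day-14 replicate 1 or 3 (adjusted p 0.0943 to 0.142, 0.0322 to 0.142 over all alternatives).

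The cell cycle and matrix lists were not called at day 14. Cell cycle genes had 0 higher and 0 lower of 30 (median −0.07, camera adjusted p = 0.662, 0 up and 0 down adjusted over the list alone), and Mki67 stood at −0.01 ± 0.44 (adjusted p = 0.996). Matrix genes had 2 higher and 1 lower of 29 (median 0.18, camera adjusted p = 0.566, 5 up and 4 down adjusted over the list alone), and Col1a1 stood at −1.13 ± 0.31 (adjusted p = 0.0848). Schwann cell genes were lower as a list with 1 of 16 called, Cdh19 (−1.36 ± 0.26) (median −0.43, camera adjusted p = 0.0165, adjusted p = 0.453 with an estimated correlation, 2 up and 4 down adjusted over the list alone). Neurotrophic genes were lower as a list, 3 down and 1 up of 16 (median −0.47, camera adjusted p = 0.0210, adjusted p = 0.453 with an estimated correlation, 3 up and 6 down adjusted over the list alone), though Bdnf itself rose (3.96 ± 0.69). Urothelial genes had 1 up and 1 down of 25 (median 0.07, camera adjusted p = 0.200, 4 up and 1 down adjusted over the list alone), the lower being the superficial cell keratin Krt20 (−1.31 ± 0.29). Of the smooth muscle genes 1 of 23 was called, Itga8 (2.77 ± 0.55) (median −0.09, mean 0.13, tested direction higher, camera adjusted p = 0.825, 1 up and 0 down adjusted over the list alone). Endothelial markers were higher as a list with 0 of 14 called (median 0.37, camera adjusted p = 0.0164, adjusted p = 0.755 with an estimated correlation, 0 up and 0 down adjusted over the list alone). Hypoxia and glycolysis genes were higher with 0 of 18 called (median 0.28, camera adjusted p = 0.0422, adjusted p = 0.736 with an estimated correlation, 1 up and 0 down adjusted over the list alone). Genes of heat shock and protein folding were higher with 0 of 18 called (median 0.34, camera adjusted p = 0.00217, adjusted p = 0.736 with an estimated correlation, 0 up and 0 down adjusted over the list alone). Interstitial cell and fibroblast markers were lower with 0 of 12 called (median −0.37, camera adjusted p = 0.0422, adjusted p = 0.784 with an estimated correlation, 1 up and 3 down adjusted over the list alone). Mitochondrial respiration was lower with 1 of 27 called, Cox6c (−0.57 ± 0.08) (median −0.10, camera adjusted p = 0.0165, adjusted p = 0.755 with an estimated correlation, 0 up and 1 down adjusted over the list alone). Cdh19 lost its call without any 1 control library or day-14 replicate 1 or 2 (adjusted p 0.0555 to 0.112, 3.95e-05 to 0.112 over all alternatives). Bdnf lost significance without any 1 control library (adjusted p 0.0856 to 0.0974, 4.09e-08 to 0.0974 over all alternatives). Krt20 was not called without any 1 control library or any 1 day-14 library (adjusted p 0.0501 to 0.150, 0.000959 to 0.150 over all alternatives). Itga8 dropped out without any 1 control library or day-14 replicate 2 or 3 (adjusted p 0.0588 to 0.129, 0.000235 to 0.129 over all alternatives). Cox6c lost its call without control replicate 2 or 3 (adjusted p 0.0642 to 0.0727, 1.01e-06 to 0.0727 over all alternatives). The Schwann cell list lost its call without day-14 replicate 1 (adjusted p 0.0941, 0.00774 to 0.0941 over all alternatives). The neurotrophic list lost significance without day-14 replicate 1 (adjusted p 0.0563, 0.0107 to 0.0563 over all alternatives). The endothelial list was not called without day-14 replicate 2 (adjusted p 0.397, 0.000576 to 0.397 over all alternatives). The hypoxia list dropped out without control replicate 2 or day-14 replicate 3 (adjusted p 0.0888 to 0.290, 0.0200 to 0.290 over all alternatives). The heat shock list lost its call without day-14 replicate 3 (adjusted p 0.169, 4.71e-07 to 0.169 over all alternatives). The interstitial cell list lost its call without control replicate 3 or day-14 replicate 1 (adjusted p 0.11 to 0.422, 0.00416 to 0.422 over all alternatives). The mitochondrial list lost significance without day-14 replicate 1 or 2 (adjusted p 0.0893 to 0.132, 0.000376 to 0.132 over all alternatives).

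Genes fixed by name that were not called at day 14 included Tnc (0.27 ± 0.39), Timp1 (1.53 ± 0.53), Acta2 (0.27 ± 0.22), Des (0.35 ± 0.25) and Myh11 (−0.24 ± 0.31). The same held for Adrb3 (−1.04 ± 0.44), Chrm2 (0.44 ± 0.25), Chrm3 (0.18 ± 0.38), P2rx1 (−0.21 ± 0.40), Upk2 (−0.24 ± 0.18) and Krt5 (0.00 ± 0.48). In all, 433 genes were called at day 14, 257 higher and 176 lower, 330.0 of them with an absolute log2 fold change of at least 1. The count was 38, 16 and 22 without control replicate 1, 2 or 3 and 122 without day-14 replicate 3. A model of only the 2 groups gave 269 higher and 340.0 lower.

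Day 28 asked how the bladder stood in the fourth week. Ly6al and Muc4 had the largest named rises and Olig1 and Krt20, a superficial urothelial keratin, the largest named falls. Ly6al (chromosome 7, 116557519 to 116561058) rose from 0.324 ± 0.292 to 369.6 ± 315 CPM (10.15 ± 0.94, adjusted p = 0.000111). The membrane mucin Muc4 (chromosome 11, 71242973 to 71285217) rose to 370.1 ± 623 CPM (10.10 ± 2.13) and the alarmin Il1a (chromosome 3, 121824712 to 121836122) by 8.28 ± 1.58. The epithelial metalloproteinase Mmp7 (chromosome 8, 5893253 to 5900965) rose by 8.01 ± 1.48 and the ubiquitin-like modifier Ubd (chromosome 20, 1876175 to 1878126) by 7.44 ± 0.85. The neutrophil chemokine Cxcl6 (chromosome 14, 18860201 to 18920839) had 2633 against 8 counts (8.16 ± 2.11, adjusted p = 0.0202), a ratio of 304 with a 95% interval of 154 to 704.5. Krt20 (chromosome 10, 87342514 to 87351045) fell from 67.4 ± 10.1 to 1.14 ± 0.509 CPM (−5.88 ± 0.37). The transcription factor Olig1 (chromosome 11, 31428377 to 31430519) had 3 counts against 1790.0 in controls (−9.16 ± 0.77), a ratio of 0.00155 with a 95% interval of 0.000319 to 0.00453. The potassium channel Kcnb2 (chromosome 5, 2975934 to 3430837) stood at −3.86 ± 0.44 and Scube2 (chromosome 1, 174428056 to 174495356) at −3.62 ± 0.35. Aldh3a1 stood at −3.46 ± 0.40 and the neuronal adhesion gene Cntnap2 (chromosome 4, 74700539 to 77025463) at −3.41 ± 0.32. Cxcl6 lost its call without any 1 control library or day-28 replicate 3 (adjusted p 0.0550 to 0.0775, 0.000135 to 0.0775 over all alternatives). The log2 value moved by over 1.5 times for Muc4 (4.95 without day-28 replicate 3).

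Most tested T, NK, B and plasma cell markers were called higher at day 28. T and NK cell markers rose in 15 of 16 cases (median 2.97, camera adjusted p = 6.00e-11, adjusted p = 0.453 with an estimated correlation, 16 up and 0 down adjusted over the list alone). Among them were the T cell kinases Lck (3.37 ± 0.33) and Zap70 (2.97 ± 0.41). B and plasma cell markers rose in 6 of 7 cases (median 3.77, camera adjusted p = 0.00201, adjusted p = 0.470 with an estimated correlation, 7 up and 0 down adjusted over the list alone). The B cell kinase Blk (4.96 ± 0.61, 281 against 8 counts, ratio 32.4, 95% interval 16.2 to 75.9) and Cd22 (1.99 ± 0.33) led them. Macrophage and myeloid markers rose in 18 of 18 cases (median 1.94, camera adjusted p = 1.43e-15, adjusted p = 0.453 with an estimated correlation, 18 up and 0 down adjusted over the list alone), with Laptm5 at 2.35 ± 0.12 and Cd68 at 2.40 ± 0.27. MHC class II genes rose in 6 of 7 cases (median 2.56, camera adjusted p = 2.16e-07, adjusted p = 0.469 with an estimated correlation, 6 up and 0 down adjusted over the list alone), with Cd74 at 2.58 ± 0.26. Neutrophil markers rose in 6 of 11 cases (median 3.90, camera adjusted p = 0.000570, adjusted p = 0.615 with an estimated correlation, 11 up and 0 down adjusted over the list alone), with Ncf1 at 3.81 ± 0.28. Cytokine and inflammatory enzyme genes rose in 20 of 28 cases (median 3.29, camera adjusted p = 1.72e-07, adjusted p = 0.615 with an estimated correlation, 25 up and 0 down adjusted over the list alone). They included the T cell attractant Ccl5 (3.71 ± 0.54), Il1b (4.50 ± 0.79) and Cxcl1 (5.64 ± 1.04). Il6 had 81 counts against 1, a ratio of 74.8 with a 95% interval of 13.1 to 2990.0 (adjusted p = 0.119). Interferon response genes rose in 5 of 20 cases (median 1.24, camera adjusted p = 0.00842, adjusted p = 0.805 with an estimated correlation, 9 up and 0 down adjusted over the list alone), with the interferon-induced Ifi47 at 1.99 ± 0.37. Mast cell markers were called in 3 of 10 cases and not as a list (median 0.60, camera adjusted p = 0.145, 4 up and 0 down adjusted over the list alone).

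Cell cycle genes rose in 15 of 30 cases at day 28 (median 1.35, camera adjusted p = 3.70e-06, adjusted p = 0.718 with an estimated correlation, 17 up and 0 down adjusted over the list alone). Ccna2 stood at 2.24 ± 0.42, Tpx2 at 1.62 ± 0.31 and Mki67 at 2.16 ± 0.44. Endothelial markers rose in 8 of 14 cases (median 0.67, camera adjusted p = 4.56e-05, adjusted p = 0.604 with an estimated correlation, 11 up and 0 down adjusted over the list alone), with the receptor Tie1 at 1.16 ± 0.23. Smooth muscle genes were lower as a list, 4 down and 1 up of 23 (median −0.62, camera adjusted p = 0.000108, adjusted p = 0.755 with an estimated correlation, 1 up and 6 down adjusted over the list alone). Smoothelin (Smtn), a marker of contractile smooth muscle, stood at −1.02 ± 0.24 and Itga8 at 2.62 ± 0.55. Matrix genes were split, 6 up and 3 down of 29 (median 0.05, camera adjusted p = 0.997, 7 up and 4 down adjusted over the list alone). Tgfb1 stood at 1.39 ± 0.13, Cthrc1 at 2.47 ± 0.44, lumican (Lum) at −0.97 ± 0.19 and Col1a1 at −1.14 ± 0.31 (adjusted p = 0.0258). Urothelial genes were split, 5 up and 5 down of 25 (median 0.24, mean −0.02, tested direction higher, camera adjusted p = 0.825, 6 up and 5 down adjusted over the list alone). The tight junction protein Tjp3 stood at 1.55 ± 0.18, Upk1a at −0.94 ± 0.14 and Upk2 at −1.17 ± 0.18. Neurotrophic genes had 5 lower and 2 higher of 16 (median −0.35, camera adjusted p = 0.111, 2 up and 6 down adjusted over the list alone). Fry called the neurotrophic list lower (fry adjusted p = 0.00561). Gfra1 stood at −2.1 ± 0.17, Cntfr at −1.99 ± 0.32 and Bdnf at 3.54 ± 0.69. Receptors and channels were 6 up and 7 down of 39 (median 0.01, mean −0.02, tested direction lower, camera adjusted p = 0.825, 9 up and 9 down adjusted over the list alone). Ednra stood at 1.69 ± 0.23, the large-conductance potassium channel Kcnma1 at −1.32 ± 0.19 and Adrb3 at −1.69 ± 0.45. Col1a1 lost its call without control replicate 1 or 3 or day-28 replicate 1 or 3 (adjusted p 0.0530 to 0.0893, 0.00139 to 0.0893 over all alternatives). Adrb3 lost significance without any 1 control library or day-28 replicate 2 or 3 (adjusted p 0.0518 to 0.0839, 0.00107 to 0.0839 over all alternatives).

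Mesothelial markers were lower as a list at day 28 with 1 of 9 called, the uroplakin Upk3b (−1.43 ± 0.26) (median −1.43, camera adjusted p = 0.0105, adjusted p = 0.736 with an estimated correlation, 0 up and 1 down adjusted over the list alone). Circadian genes were lower as a list, 3 down and 1 up of 17 (median −0.47, camera adjusted p = 0.0474, adjusted p = 0.718 with an estimated correlation, 2 up and 5 down adjusted over the list alone). Schwann cell genes had 2 higher and 4 lower of 16 (median 0.06, mean 0.23, tested direction lower, camera adjusted p = 0.662, 3 up and 4 down adjusted over the list alone), with Cdh19 at −1.56 ± 0.26. Genes fixed by name and not called were Tnc (−0.57 ± 0.39), Timp1 (1.55 ± 0.53), Acta2 (−0.45 ± 0.22), Des (−0.36 ± 0.25) and Myh11 (−0.79 ± 0.31). Chrm2 (0.47 ± 0.25), Chrm3 (−0.36 ± 0.38), P2rx1 (−0.70 ± 0.40) and Krt5 (1.39 ± 0.49) were not called either. In all, 3275 genes were called at day 28, 1946 higher and 1329 lower, 1835 of them with an absolute log2 fold change of at least 1. The count was 1971 without control replicate 2 and 2015 without control replicate 3. The mesothelial list lost its call without day-28 replicate 1 (adjusted p 0.0553, 0.00315 to 0.0553 over all alternatives). The circadian list lost significance without control replicate 3 or day-28 replicate 2 or 3 (adjusted p 0.0868 to 0.131, 0.0154 to 0.131 over all alternatives). Of the 43 list calls in 102 tests (32 higher and 11 lower), 0 held with an estimated correlation and 20 by fry. Fry called 23 in all, 5 at day 14.

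**Figure D1:**
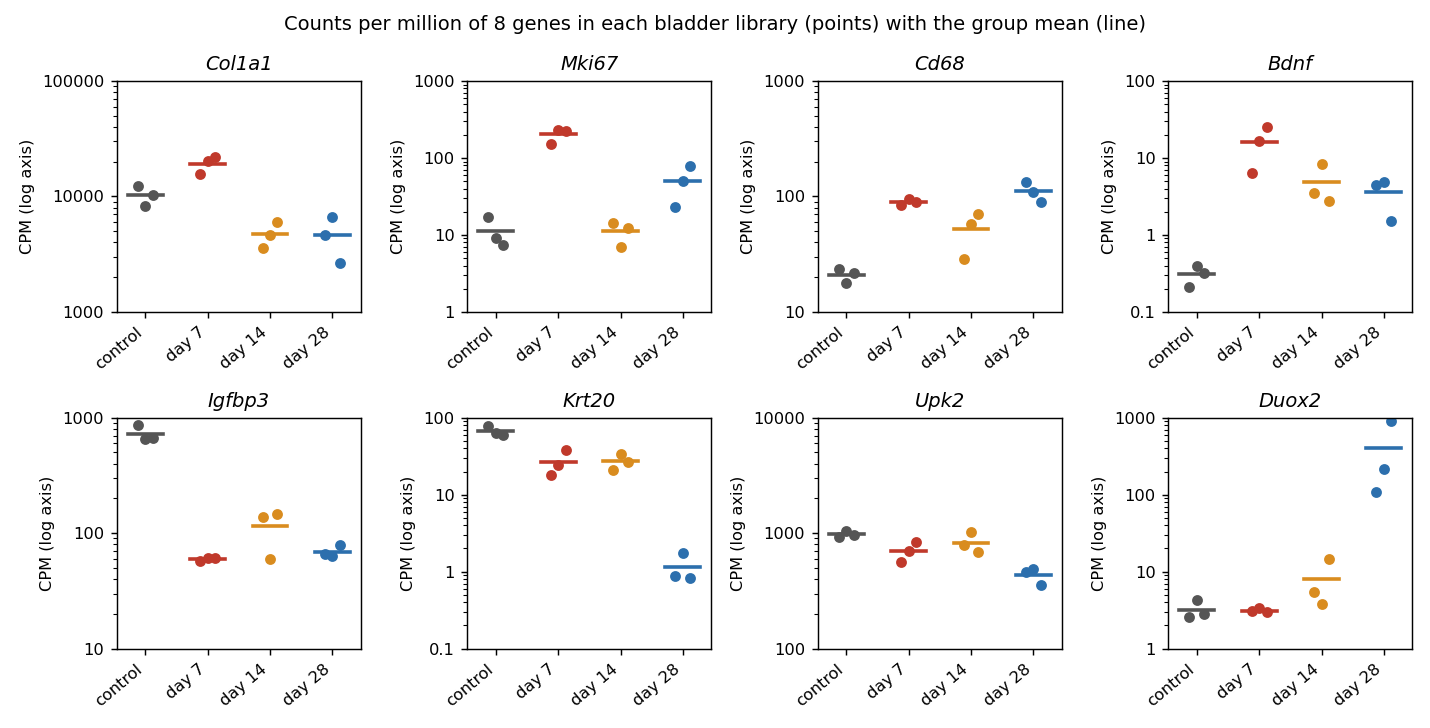
CPM on log axes of 8 genes in the 3 libraries of each group (points) with the group mean (line). Mean Mki67 was 11.2, 202, 11.2 and 50.4 CPM in controls and at days 7, 14 and 28, and mean Krt20 was 67.4, 27.0, 27.1 and 1.14 CPM.

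**Figure D2:**
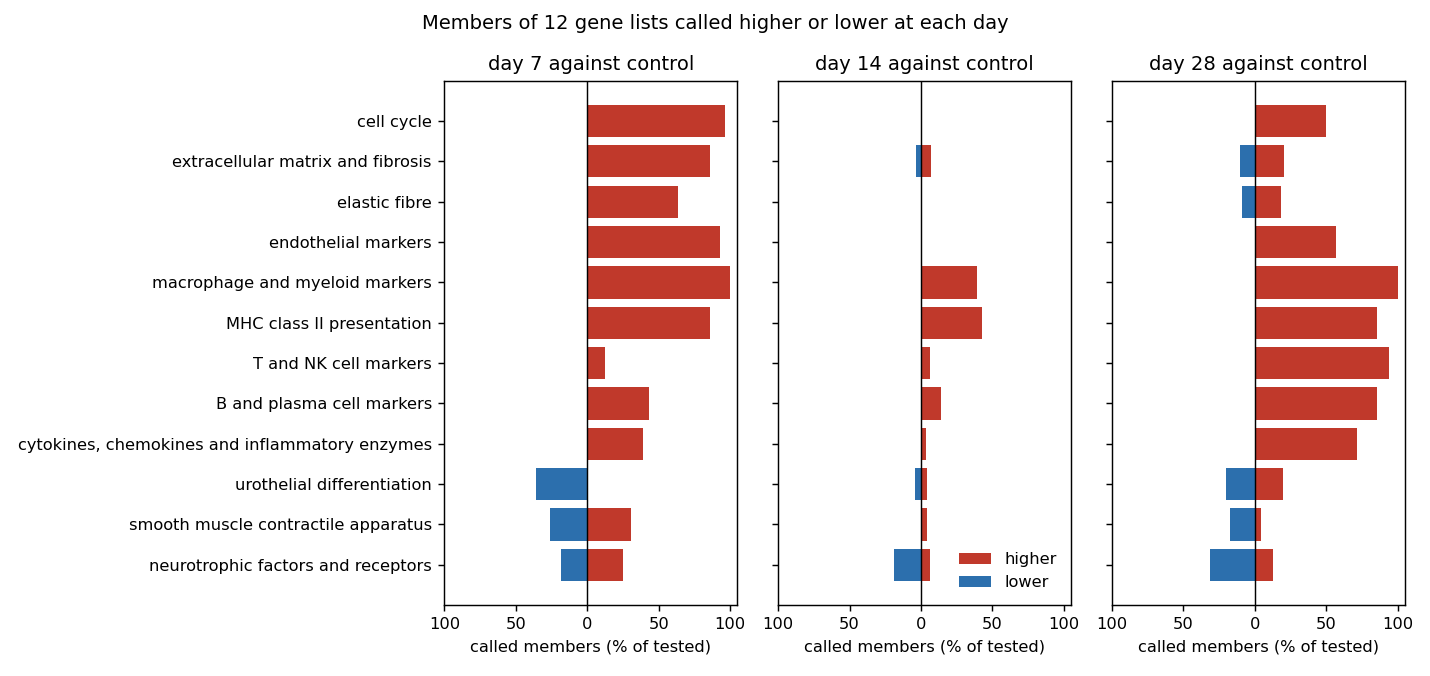
Members of 12 gene lists called higher (red bars, to the right) or lower (blue bars, to the left) than control at each day, as a percentage of the members tested. Cell cycle genes show 29, 0 and 15 of 30 higher at days 7, 14 and 28, and T and NK cell markers 2, 1 and 15 of 16.

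The days were then compared with one another to see which changes differed with time. From day 7 to day 14, Tnn fell from 142 ± 115 to 0.282 ± 0.192 CPM (−8.95 ± 0.93). The red-cell anion exchanger Slc4a1 (chromosome 10, 90296144 to 90312401) stood at −6.72 ± 1.39 and the lipoxygenase Alox15 (chromosome 10, 56953692 to 56962145) at −6.11 ± 1.30. The serine protease relative Prss35 (chromosome 8, 94423629 to 94440509) stood at −5.31 ± 0.88. Cyp1a1 rose by 5.15 ± 1.12, the collagenase Mmp13 (chromosome 8, 5522739 to 5533018) by 3.93 ± 1.08 and Galnt9 (chromosome 12, 52106506 to 52187205) by 3.56 ± 0.56. The macrophage elastase Mmp12 (chromosome 8, 5594717 to 5616494) rose by 3.30 ± 0.88 and Mamdc2 by 2.74 ± 0.58. Among the genes fixed by name, Col1a1 (−2.03 ± 0.32), Tnc (−2.79 ± 0.42), Timp1 (−2.29 ± 0.54), Bdnf (−1.73 ± 0.56) and Mki67 (−4.17 ± 0.48) fell. The test called 3457 genes, 1343 higher and 2114 lower at day 14. There were 1959 without day-7 replicate 2, 2160.0 without day-14 replicate 1 and 2195 with only these 2 groups in the model. Mmp13 lost its call without any 1 day-7 library or day-14 replicate 3 (adjusted p 0.0648 to 0.0826, 0.00112 to 0.0826 over all alternatives). Mmp12 lost significance without any 1 day-7 library or day-14 replicate 1 or 3 (adjusted p 0.0536 to 0.0683, 0.00138 to 0.0683 over all alternatives). Timp1 was not called with only the 2 groups fitted (adjusted p 0.0554, 0.000978 to 0.0554 over all alternatives). Bdnf dropped out without day-7 replicate 2 or 3 or day-14 replicate 1 or 3, with size factors and with only the 2 groups fitted (adjusted p 0.0504 to 0.185, 0.010 to 0.185 over all alternatives). The log2 value moved by over 1.5 times for Slc4a1 (−3.97 without day-7 replicate 3), Alox15 (−3.39 without day-7 replicate 3) and Mamdc2 (4.12 without day-7 replicate 1).

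The largest named rises from day 14 to day 28 were those of Muc4, by 9.64 ± 2.06, Ly6al, by 9.05 ± 0.87, and the mucin Muc20 (chromosome 11, 71222602 to 71236223), by 6.23 ± 1.01. The epithelial oxidase Duox2 (chromosome 3, 114218187 to 114237808), which overlaps its maturation factor Duoxa2, rose by 5.68 ± 0.79. Gkn3 (chromosome 4, 119181970 to 119188356), of the gastrokine family, rose by 4.88 ± 0.87. Olig1 had 3 counts at day 28 against 438 at day 14 (−7.11 ± 0.78), a ratio of 0.00637 with a 95% interval of 0.00131 to 0.0187. Krt20 fell from 27.1 ± 6.07 to 1.14 ± 0.509 CPM (−4.57 ± 0.36). The immediate early gene Fosb (chromosome 1, 80214691 to 80221417, −3.73 ± 0.78), Kcnb2 (−3.44 ± 0.43) and Scube2 (−3.17 ± 0.35) fell too. Mki67 (2.17 ± 0.44) and Cd68 (1.08 ± 0.26) rose and Upk2 (−0.93 ± 0.18) fell. The test called 768 genes, 553 higher and 215 lower, but 42 with only these 2 groups in the model. Without day-14 replicate 1 or 2 the count was 367 or 313, and without day-28 replicate 2 or 3 it was 261 or 345. Muc4 lost its call without any 1 day-14 library and with only the 2 groups fitted (adjusted p 0.0632 to 0.149, 0.00381 to 0.149 over all alternatives). Muc20 lost significance with only the 2 groups fitted (adjusted p 0.0807, 9.77e-07 to 0.0807 over all alternatives). Duox2 was not called with only the 2 groups fitted (adjusted p 0.0694, 8.39e-11 to 0.0694 over all alternatives). Gkn3 dropped out with only the 2 groups fitted (adjusted p 0.101, 1.57e-06 to 0.101 over all alternatives). Fosb lost its call without day-14 replicate 1 or day-28 replicate 2 or 3 and with only the 2 groups fitted (adjusted p 0.0566 to 0.0899, 0.000136 to 0.0899 over all alternatives). Kcnb2 lost its call with only the 2 groups fitted (adjusted p 0.0634, 2.74e-14 to 0.0634 over all alternatives). Mki67 lost significance without day-14 replicate 2 or day-28 replicate 2 or 3 and with only the 2 groups fitted (adjusted p 0.0617 to 0.0982, 1.29e-05 to 0.0982 over all alternatives). Cd68 was not called without day-14 replicate 1 or 2 or any 1 day-28 library and with only the 2 groups fitted (adjusted p 0.0540 to 0.178, 0.00246 to 0.178 over all alternatives). Upk2 dropped out without day-14 replicate 2 or day-28 replicate 3 and with only the 2 groups fitted (adjusted p 0.0638 to 0.0900, 0.000106 to 0.0900 over all alternatives). The log2 value moved by over 1.5 times for Muc4 (4.49 without day-28 replicate 3).

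Between day 7 and day 28 the matrix and proliferation genes fixed by name were lower at the later day. Col1a1 stood at −2.05 ± 0.32, Tnc at −3.63 ± 0.43, Timp1 at −2.27 ± 0.54 and Mki67 at −2.0 ± 0.43. Acta2 (−1.25 ± 0.22), Des (−1.47 ± 0.25), Bdnf (−2.15 ± 0.57) and Upk2 (−0.69 ± 0.18) were lower as well. The test called 3310.0 genes, 1395 higher and 1915 lower at day 28. The count was 1954 without day-7 replicate 2, 2163 without day-7 replicate 3 and 2112 without day-28 replicate 3. Bdnf lost its call without day-7 replicate 2 or 3 or day-28 replicate 3 and with only the 2 groups fitted (adjusted p 0.0540 to 0.0881, 0.000852 to 0.0881 over all alternatives). Upk2 lost significance without day-7 replicate 2 or 3 or day-28 replicate 3 and with only the 2 groups fitted (adjusted p 0.0529 to 0.0896, 0.00355 to 0.0896 over all alternatives).

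Genes called against control at all 3 days numbered 204 higher and 99 lower, where independent lists of these sizes would share 4.41 and 1.39. Pairs of days shared 218 higher genes (days 7 and 14, 40.1 if independent), 1018 (days 7 and 28, 303 if independent) and 236 (days 14 and 28, 28.3 if independent). The lower genes shared numbered 110.0, 673 and 147 in that order (18.6, 140.1 and 13.2 if independent). Because the 3 comparisons share the 3 controls, 20 draws of unchanged groups were simulated against them and gave at most 0 genes at all 3 days. Across 17687 genes, which are not independent replicates, the fold changes correlated at 0.596, 0.644 and 0.739 in that order of days, against 0.507, 0.505 and 0.510 with no effect. The covariances were 0.496, 0.743 and 0.617 against 0.0979, 0.0970 and 0.0979. The 3 controls could not be split with at least 2 in each part, so part of the excess can come from sharing them. Without control replicate 1, 2 or 3 the genes called at all 3 days numbered 30.0, 11 or 17, and without day-7 replicate 2 or day-14 replicate 3 they numbered 189 or 102. Genes called in opposite directions at 2 days numbered 50.0 for days 7 and 28 (33 higher then lower), 7 for days 7 and 14 and 1 for days 14 and 28.

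The title of the series sets long non-coding RNA at its centre. H19, an imprinted transcript abundant in fetal tissue, rose from 3.24 ± 1.78 to 79.4 ± 8.85 CPM at day 7 (4.62 ± 0.43, adjusted p = 3.11e-05). It stood at 7.60 ± 2.63 CPM at day 14 and 16.2 ± 8.15 CPM at day 28 (2.32 ± 0.40). The imprinted Meg3 rose from 18.4 ± 1.80 to 74.1 ± 10.3 CPM at day 7 (2.01 ± 0.21) and was lower than control at day 28 (−1.09 ± 0.21). Mir155hg, the host of an immune-cell microRNA, rose by 2.22 ± 0.63 at day 7 and 2.68 ± 0.62 at day 28. Xist, which silences 1 X chromosome in female cells, was lower at day 7 (1525 ± 148 against 2094 ± 182 CPM, −0.46 ± 0.10). Miat had 4 counts at day 28 against 52 (−3.69 ± 1.02, ratio 0.0710, 95% interval 0.0187 to 0.193). A transcript of Snhg11, typed as a protein-coding gene, had 3 counts at day 7 against 42 (−3.64 ± 1.21, ratio 0.0719, 0.0143 to 0.225). Gas5, Oip5-as1, Pvt1 and Tug1 were not called at any day, and 10 of the 29 names listed had a tested transcript. Mir155hg at day 7 lost its call without any 1 control library or day-7 replicate 2 (adjusted p 0.0598 to 0.124, 0.0195 to 0.124 over all alternatives). Mir155hg at day 28 lost significance without day-28 replicate 3 (adjusted p 0.0508, 0.00295 to 0.0508 over all alternatives). Xist was not called with own library totals (adjusted p 0.142, 1.87e-05 to 0.142 over all alternatives). Miat dropped out without control replicate 2 or 3 or day-28 replicate 1 or 3 (adjusted p 0.0704 to 0.0892, 0.000683 to 0.0892 over all alternatives). Snhg11 lost its call without any 1 control library or any 1 day-7 library, with own library totals and with 1 transcript per gene (adjusted p 0.0542 to 0.159, 0.0110 to 0.159 over all alternatives).

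**Figure D3:**
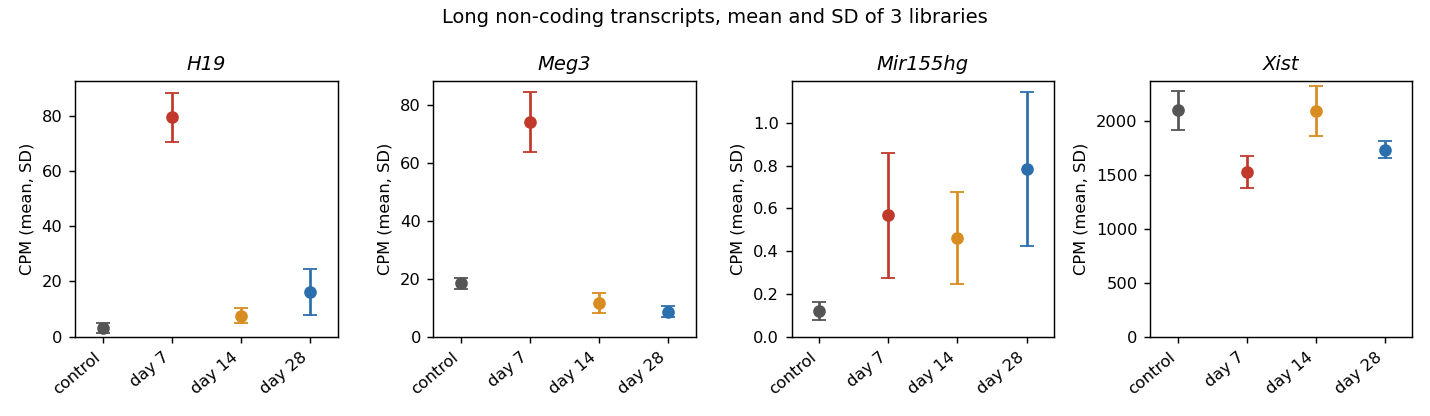
Mean CPM (points) with the SD of 3 libraries (bars) of the long non-coding transcripts H19, Meg3, Mir155hg and Xist in controls and at each day. H19 is at 3.24 ± 1.78 CPM in controls and 79.4 ± 8.85 CPM at day 7, and Meg3 at 18.4 ± 1.80 and 74.1 ± 10.3 CPM.

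Besides H19, a non-coding transcript of Ankle1 (2810.0 bases) rose by 4.43 ± 0.51 at day 7. LOC100359539 (2541 bases) rose by 4.42 ± 0.67, and a non-coding transcript of the leukocyte receptor Lilrb4 (1133 bases) by 4.01 ± 0.63. Ankle1 and Lilrb4 are protein-coding genes, whose mRNA reads these counts can include. LOC108351270 stood at −3.94 ± 0.42, the 1012-base and 1032-base transcripts of LOC108350681 at −3.85 ± 0.49 and −3.50 ± 0.43, and LOC680627 at −3.76 ± 0.44. At day 28 LOC100359515 had 340.0 counts against 1 (7.83 ± 1.94), a ratio of 313.9 with a 95% interval of 56.0 to 12430.0. LOC100910084 had 808 against 7 counts (6.66 ± 1.71, ratio 106.6, 51.5 to 265.9) and LOC102554317 267 against 6 (5.27 ± 0.69, ratio 41.1, 18.6 to 112.9). Lilrb4 rose by 4.83 ± 0.64 at day 28. LOC102549616 (−3.45 ± 0.64), ENSRNOG00000057008.1 (−3.35 ± 0.81), LOC108349910 (−2.98 ± 0.73) and LOC108350787 (−2.88 ± 0.50) had the largest falls at day 28 among called transcripts with a mean of at least 1 CPM and all 3 injured libraries outside the range of the controls. LOC100359515 lost its call without any 1 control library (adjusted p 0.0672 to 0.0720, 1.00e-25 to 0.0720 over all alternatives). LOC100910084 lost significance without any 1 control library (adjusted p 0.0725 to 0.0798, 5.57e-58 to 0.0798 over all alternatives). LOC108349910 was not called without day-28 replicate 2 (adjusted p 0.0589, 3.92e-08 to 0.0589 over all alternatives).

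At day 14 Lilrb4 rose by 3.59 ± 0.63 and the 1733-base and 1716-base transcripts of LOC103691468 by 3.59 ± 0.51 and 3.56 ± 0.50. LOC102554317 had 60.0 against 6 counts (3.24 ± 0.72, ratio 9.92, 95% interval 4.30 to 28.1). ENSRNOG00000060407.2 stood at −2.98 ± 0.44, LOC680627 at −2.23 ± 0.39 and the 1452-base and 2016-base transcripts of ENSRNOG00000061982.1 at −2.0 ± 0.44 and −1.94 ± 0.41. Of these 8 calls, 0 held with every library omitted in turn. Lilrb4 lost its call without any 1 control library or day-14 replicate 3 (adjusted p 0.0549 to 0.0688, 7.52e-41 to 0.0688 over all alternatives). The 1733-base LOC103691468 transcript lost significance without control replicate 2 (adjusted p 0.0574, 1.28e-14 to 0.0574 over all alternatives). The 1716-base LOC103691468 transcript was not called without control replicate 2 (adjusted p 0.0574, 2.35e-14 to 0.0574 over all alternatives). LOC102554317 dropped out without control replicate 1 or 2 or day-14 replicate 1 or 3 and with only the 2 groups fitted (adjusted p 0.0554 to 0.155, 3.55e-05 to 0.155 over all alternatives). ENSRNOG00000060407.2 lost its call without control replicate 2 (adjusted p 0.0574, 9.52e-08 to 0.0574 over all alternatives). LOC680627 lost its call without control replicate 2 or 3 or day-14 replicate 3 (adjusted p 0.0550 to 0.0688, 1.33e-10 to 0.0688 over all alternatives). The 1452-base ENSRNOG00000061982.1 transcript lost significance without any 1 control library or day-14 replicate 2 or 3 (adjusted p 0.0714 to 0.159, 0.00188 to 0.159 over all alternatives). The 2016-base ENSRNOG00000061982.1 transcript was not called without any 1 control library or day-14 replicate 2 or 3 (adjusted p 0.0613 to 0.144, 0.00165 to 0.144 over all alternatives). The log2 value moved by over 1.5 times for LOC102554317 (5.01 without control replicate 3).

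Of 3911 tested transcripts, 708 were called at day 7 (264 higher and 444 lower), 84 at day 14 (51 and 33) and 535 at day 28 (257 and 278). Of these calls 219, 24 and 177 are transcripts of protein-coding genes and can carry reads of the coding mRNA. With library totals from the non-coding table itself, the split was 357 higher and 265 lower at day 7, 54 and 33 at day 14 and 298 and 251 at day 28. That scaling moved the median fold change by 0.186 at day 7 and 0.08 at day 28. The balance also turned at each day when certain single libraries were left out. At day 7 the count was 423, 429 or 361 without control replicate 1, 2 or 3 and 360.0 or 381 without day-7 replicate 2 or 3. At day 14 it was 11, 0 or 10 without control replicate 1, 2 or 3 and 54 or 8 without day-14 replicate 2 or 3. Where edgeR called 0, 457 had an unadjusted p under 0.05. At day 28 it was 341 without control replicate 2. The authors' deposited tables mark 633 non-coding transcripts as different at day 7, 155 at day 14 and 553 at day 28. Of those in the authors' deposited tables, 524, 144 and 466 were tested here and 414, 63 and 355 called, 0 of them in the opposite direction.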

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

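Apart from the tests between days and the thinning of counts, the tests in this part were chosen after the results had been seen. Differences between days stood out: the tests between days called 3457 genes (days 14 and 7), 768 (days 28 and 14) and 3310.0 (days 28 and 7), and 50.0, 7 and 1 genes were called in opposite directions against control at days 7 and 28, 7 and 14, and 14 and 28. From day 7 to day 14 the log2 fold change was 5.15 for Cyp1a1, 3.93 for Mmp13, 3.56 for Galnt9, 3.30 for Mmp12, 2.74 for Mamdc2, −8.95 for Tnn, −6.72 for Slc4a1, −6.11 for Alox15, −5.31 for Prss35, −2.03 for Col1a1, −2.79 for Tnc, −2.29 for Timp1, −1.73 for Bdnf and −4.17 for Mki67. From day 14 to day 28 it was 9.64 for Muc4, 9.05 for Ly6al, 6.23 for Muc20, 5.68 for Duox2, 4.88 for Gkn3, −7.11 for Olig1, −4.57 for Krt20, −3.73 for Fosb, −3.44 for Kcnb2, −3.17 for Scube2, −0.93 for Upk2, 2.17 for Mki67 and 1.08 for Cd68. From day 7 to day 28 it was −2.05 for Col1a1, −3.63 for Tnc, −2.27 for Timp1, −1.25 for Acta2, −1.47 for Des, −2.15 for Bdnf, −0.69 for Upk2 and −2.0 for Mki67. Without 1 library the value moved by over 1.5 times for Mamdc2, Slc4a1, Alox15 and Muc4. The calls of Mmp13, Mmp12, Timp1 and Bdnf between days 14 and 7, of Muc4, Muc20, Duox2, Gkn3, Fosb, Kcnb2, Upk2, Mki67 and Cd68 between days 28 and 14, and of Bdnf and Upk2 between days 28 and 7 were lost in at least 1 alternative, named in the report.

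Day 14 had the fewest calls, 433 against 4622 at day 7 and 3275 at day 28. A wider spread between the day-14 libraries as the cause is argued against by the median SE, 0.207 at days 7, 14 and 28. All libraries shared 1 model. Genes with an absolute log2 fold change of at least 1, whatever their p, numbered 3455, 1863 and 2977 at these days. The measured spread was slightly wider at day 14 (median SD 0.231 log2 CPM against 0.222 and 0.223). A control library labelled as day 14 is argued against by distance, the closest day-14 library lying 0.690 from the controls in log2 CPM and the farthest control 0.476. With every library thinned to the smallest day-14 total of 26.3 M, 4587, 394 and 3216 genes were called at days 7, 14 and 28, so lower depth at day 14 did not account for the low count. The time since injury, which the design names, stays open and untested.

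Erythroid transcripts were higher at day 7. Day-7 replicate 3 alone cannot be told apart from a wider rise: 0 of the 10 erythroid genes were still called without it by edgeR, but all 10 stayed higher (log2 fold change 0.59 to 2.51), and replicates 1 and 2 had 0.156% and 0.370% haemoglobin transcripts against 0.0636% to 0.286% in controls. More blood of unchanged make-up stays open: the ratio of non-globin to globin red-cell transcripts was at least 1.85% at day 7 against at most 1.45% in controls, but the means (1.27% ± 0.20 and 1.96% ± 0.11) lay closer than the SD of 1.16 at day 14 (mean 2.71%), and at day 28 the mean was 1.45% ± 0.20. A change in the blood itself stays open and untested.

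Muc4, Muc20, Duox2 and Gkn3 were higher and Krt20 lower at day 28 than at day 14, a pattern read from the named genes with no fixed list behind it. Intestinal or gastric epithelium in the samples is argued against by its abundant transcripts, as 5 of 24 measured genes of that kind, from a list written after the pattern was seen, reached 1 CPM (5 did in controls), while Fabp1, Fabp2, Pgc and Atp4a were at or below 0.0111 CPM at day 28 and Vil1, Lgals4, Gkn1 and Gkn2 were called higher. The uroplakins argue against an even loss of urothelium as the whole cause of the Krt20 fall. Krt20, picked for its fall, differed from them by at least 4.71 in log2 (Upk2, SE 0.414). A first, tighter bound, 0.25 of the Krt20 change, was missed by Upk2 and then replaced. A part or an uneven loss stays open. Epithelium of the female reproductive tract stays open, as 2 of its 5 tested markers were called higher at day 28 (Olfm4 and Pax8, the latter not without control replicate 2, adjusted p 0.0567) and 3 were not, which are too few to decide. The share of day-28 replicate 3 cannot be tested on genes named for having all 3 libraries outside the control range. Without it Muc4 against control moved from 10.10 to 4.95. A change of the urothelium with time stays open and untested.

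The 10 splits of 3 with 3 libraries are too few for a share under 0.05. Splits other than the real one mix the groups, turning a real difference into spread, so their low counts decide nothing. The real count and highest other were 4622 and 1, 433 and 0, and 3275 and 0 at days 7, 14 and 28. Between days 14 and 7, 28 and 14, and 28 and 7 they were 3457 and 13, 768 and 2, and 3310.0 and 1. Non-coding transcripts gave 708 and 1, 84 and 0, and 535 and 0 at days 7, 14 and 28.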

How the results depend on the processing

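Own library totals, 1 transcript per gene, long non-coding types alone, and leaving out libraries for the lists and for the genes called at all 3 days, were chosen after the data had been seen. None of the 388 called results for named genes and transcripts and of the 43 list calls changed direction in a setting run for it, and other called genes were not followed. Uncalled named results changed sign 101 times when libraries were left out, 11 with own library totals, 9 with the replicate block, 4 with RLE size factors, 3 with DESeq2, 1 with no filter and 1 with a mean of at least 5 CPM. The balance of gene calls turned at day 14 from 257 higher and 176 lower to 269 and 340.0 with only the 2 groups and to 16 and 22 or 6 and 10.0 without control replicate 1 or 2, and stood at 11 and 11 without replicate 3. Genes called at all 3 days went from 204 and 99 to 14 and 16 or 5 and 6 without control replicate 1 or 2. Transcripts at day 7 went from 264 and 444 to 357 and 265 with own totals and to 188 and 172 or 202 and 179 without day-7 replicate 2 or 3. At day 14 they went from 51 and 33 to 39 and 61 with only the 2 groups, 26 and 33 with long non-coding types and 3 and 8 without control replicate 1. At day 28 they went from 257 and 278 to 298 and 251 with own totals and turned also with 1 transcript per gene, at an absolute log2 fold change of at least 1 and without control replicate 2 or 3 or any 1 day-28 library (180.0 and 161 to 275 and 246). RLE size factors moved no count of calls by over 1.5 times. Genes called with DESeq2 numbered 1302 at day 14 and 1609 between days 28 and 14, and 752 at all 3 days. An absolute log2 fold change of at least 1 left 2346, 1835, 1470.0, 472 and 1591 genes at day 7, at day 28 and between days 14 and 7, 28 and 14, and 28 and 7, and 468 transcripts at day 7, since fewer could pass. With a mean of at least 5 CPM there were 251 genes at day 14 and 350.0, 36 and 282 transcripts at days 7, 14 and 28, and with no filter 232 transcripts at day 14. Only the 2 groups compared gave 2195 genes between days 14 and 7 and 42 between days 28 and 14. One transcript per gene gave 403, 43 and 293 transcripts at the 3 days and long non-coding types 421 and 321 at days 7 and 28, fewer being tested. Leaving out 1 library gave 3061 to 4888 genes at day 7, 16 to 504 at day 14, 1971 to 3283 at day 28, 1959 to 3431 between days 14 and 7, 261 to 1120.0 between days 28 and 14, 1954 to 3275 between days 28 and 7, 360.0 to 764, 0 to 70.0 and 341 to 521 transcripts at days 7, 14 and 28, 11 to 386 genes at all 3 days and 39 to 43 list calls. List calls were 0 with an estimated correlation and 23 by fry. Apart from smaller sets or fewer samples, the cause was not tested. Of 388 called named results, 240.0 kept their call in every setting and 148 lost it in at least 1, and leaving out libraries ended 525 of 2328 calls of named genes and transcripts and 24 of 258 list calls and added 39 calls in 1656 cases not called. With the replicate number as a block, genes called numbered 4788, 460.0, 3440.0, 3662, 827 and 3463 in the order above, transcripts 712, 96 and 573, genes at all 3 days 353 and list calls 46. Same-numbered libraries correlated at −0.0216 to 0.151 in their deviations, 13 of 18 pairs not above 0.1, so by that limit the numbers do not pair the libraries, although 9 of 12 correlated best with their own number. The pseudocount alternative does not apply to counts. Depth of 26.3 to 30.7 M limits mainly genes at a few counts.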

Other observations

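Some lists that were not called at the day given held called genes. Adipocyte markers at day 7 were called higher in 8 and lower in 3 of 16 cases (median 1.65, camera adjusted p = 0.368, 8 up and 4 down adjusted over the list alone), with the hormone-sensitive lipase Lipe at 1.03 ± 0.17, the adipokine Cfd at 2.28 ± 0.48 and Adipoq at 7.00 ± 1.49, and at day 14 0 higher and 1 lower were called and at day 28 4 and 1. Skeletal muscle markers were higher in 4 and lower in 2 of 15 at day 7 (median 0.03, camera adjusted p = 0.997, 4 up and 2 down adjusted over the list alone), with skeletal actin Acta1 at 4.05 ± 0.48 and the glycogen phosphorylase Pygm at −2.05 ± 0.31, and at day 14 3 higher and 0 lower were called and at day 28 1 and 3. Of the markers of female reproductive tract epithelium, 2 of 5 were higher at day 7 (median 1.90, camera adjusted p = 0.188, 3 up and 0 down adjusted over the list alone), Foxj1 (1.90 ± 0.52) and Pax8 (1.85 ± 0.53). At day 14 0 of 5 were called (median 0.33, camera adjusted p = 0.982, 0 up and 0 down adjusted over the list alone), and at day 28 2 were higher (median 0.75, camera adjusted p = 0.662, 2 up and 0 down adjusted over the list alone), Olfm4 (6.39 ± 1.03, 865 against 9 counts, ratio 88.7, 95% interval 46.5 to 194.7) and Pax8 (2.27 ± 0.53). Foxj1 lost its call without control replicate 1 or 2 or day-7 replicate 3 (adjusted p 0.0767 to 0.0875, 0.00140 to 0.0875 over all alternatives). Pax8 at day 7 lost significance without any 1 control library or day-7 replicate 2 or 3 (adjusted p 0.0549 to 0.0903, 0.00727 to 0.0903 over all alternatives). Pax8 at day 28 was not called without control replicate 2 (adjusted p 0.0567, 0.000813 to 0.0567 over all alternatives).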
